A study of Homo sapiens with 8 samples.

How the data were processed

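RNA was measured in 8 samples of cultured human macrophages on Affymetrix expression arrays, 4 treated with hY3 and 4 untreated. Per the labels' protocols, 50 ng of total RNA per sample was amplified in a 2-cycle scheme and labelled with biotin. The deposited values were a single table of 54675 probe sets by 8 arrays, each an intensity on a linear scale. How the authors summarised probes and normalised the arrays is not given in the sources used here. The quartiles of the deposited intensities were nearly equal on all arrays (lower quartile 12.1 to 12.8, upper quartile 316 to 343), so the values were taken as already comparable between arrays and no further normalisation was applied. A normalisation that makes arrays alike in this way hides any change in total RNA, and values near the lower quartile cannot be told from background, since no detection calls were used.

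Probe sets were named through the platform's gene table. Of the probe sets, 41091 had exactly 1 gene symbol, 1801 had several and 11777 were unnamed here, and no symbol needed an update. The 62 control probe sets were left out, except that the 3' and 5' control probe sets of GAPDH and ACTB were used for RNA integrity. For each of the 19775 genes the probe set with the highest mean over all 8 arrays stood for the gene. 10523 genes had more than 1 probe set, and where another choice of probe set ended the call, turned the sign or moved the log2 change of a named gene past the threshold by more than 1.5 times, this is said beside the gene. Probe sets whose identifiers end in _x_at or _s_at can also bind other genes or transcripts.

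The main test was limma (version 3.58.1, R 4.3.3) on log2(intensity + 16), with lmFit and eBayes, hY3 minus untreated, all 8 arrays, no block, Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Log2 changes are on the log2(value + 16) scale, which understates the change of dim genes. Means ± SD are of the deposited intensities. The groups were taken from the labels. The design, the lists, the rule for named genes and the alternatives, save those named last, were fixed before the data were examined.

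The rule named the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold whose hY3 and untreated arrays did not overlap, up to 4 members of each gene list with the smallest adjusted p, and 14 genes whatever they showed (SIGLEC1, IFNB1, IFIT1, MX1, CXCL10, TNF, IL6, IL1B, TLR7, TLR8, RO60, TRIM21, EDN1 and TGFB1). Probe sets with several or no symbols, sex-linked control genes and immunoglobulin and T cell receptor segments were left out of naming. The rule gave 131 genes, of which 90 passed the threshold.

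There were 27 gene lists and 9 lists of cell type markers, written from textbook knowledge, with 796 entries of which 72 had no probe set of their own and were not analysed here. Some genes stand in more than 1 list, among them 12 of the 30 measured interferon-γ-associated genes, 5 of the 14 macrophage and monocyte markers and 3 of the 26 cell death genes. Lists were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 36 lists. With the correlation estimated per list none of the 19 lists past the threshold kept its call (adjusted p from 0.123 to 0.633). A larger correlation cannot be the reason for all of them. The estimate was under the preset for chemokines (-0.0026), complement (-0.019) and the Ro and La list (-0.0015), and their unadjusted p still rose. For chemokines the unadjusted camera p rose from 3.12e-05 to 0.00355. fry was run as a further test. Its adjusted p was 2.19e-04 for interferon-stimulated genes and 0.115 for type I and III interferons.

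The labels number the arrays 1 to 4 in both groups without saying what a number marks. The deviations of same-numbered arrays from their group means correlated across genes at 0.480, 0.671, 0.648 and 0.593, all above the limit of 0.1, and each array's deviations correlated best with those of its own number in the other group. The values themselves did not always: of the hY3 arrays, untreated arrays 1 and 2 correlated best with array 4 (0.976 each). The numbers were therefore taken to pair the arrays, as a pairing seen in the data and not in the labels. The main test kept no block, so its p-values ignore this pairing. Values with the number as a block are given where they changed a call or moved a count by more than 1.5 times.

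Alternatives were the array number as a fixed or random block, quantile normalisation, median centring, a filter on dim probe sets, other choices of probe set, eBayes with trend and robust, array weights, pseudocounts of 1 and 64, each array left out, all probe sets, stricter thresholds (2-fold, adjusted p of 0.01, limma's treat against 1.2-fold), an estimated correlation and fry. Fits on arrays numbered 1 and 2 or 3 and 4 alone, with these 2 sets as a block, and with the block while a number was left out, were added after the data were seen. Tested on simulated data for the comparison of hY3 with untreated (19775 genes, 5 simulations, 200 changed genes each), the main test recovered 58.6% of genes changed by 1 and 87.2% of genes changed by 2 on the log2 scale, with 5.43% false among calls, and camera called the shifted list in 5 of 5 simulations. Over the 5 simulations camera also called 1 list that shared no gene with the shifted one. The simulated noise was drawn independently for each gene and array, without pairing, and the 200 changed genes were brighter than the median. These rates therefore do not cover correlated genes, paired arrays or dim genes, and cannot vouch for the preset correlation. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.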

Results

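The data comprised 8 arrays of human macrophages that had been grown from CD14-selected blood monocytes for 7 days with 10 ng/ml GM-CSF, a growth factor that drives monocytes toward macrophages. Macrophages treated with hY3 gave 4 arrays and untreated macrophages gave 4. hY3 is a small noncoding RNA that the autoantigen Ro60 binds. The protocol mixed 2.5 µg of single-stranded RNA with 15 µl of DOTAP, a cationic lipid carrier, in 75 µl, and left it overnight on macrophages primed with interferon-γ. The labels did not state whether the untreated macrophages received the carrier or the priming, so every change below is that of RNA, carrier and any difference in priming together. The median intensity lay between 44.1 and 45.2 on all 8 arrays. The number of arrays limits the precision, and because no label ties the arrays to separate donors or cultures, p-values measure only the spread between these arrays.

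The comparison of hY3-treated with untreated macrophages asked which genes differ after hY3. All 43 measured members of the list of interferon-stimulated genes rose after hY3, with a median log2 change of 2.71, as did 22 of 30 interferon-γ-associated genes and 13 of 26 cell death genes. Of 18 cholesterol biosynthesis genes 5 fell and 1, LSS, rose, and of 30 cell cycle genes 4 fell. The calls of these lists were lost with an estimated correlation (adjusted p = 0.123 for each of the first 3, 0.198 for cholesterol biosynthesis and 0.317 for cell cycle), and a ratio that rises with RNA degradation was higher on the hY3 arrays. On the log2(value + 16) scale the largest rise was that of ISG20, an exonuclease induced by interferon, with a log2 change of 7.32. Its intensity went from 36.7 ± 14.3 to 8395 ± 2135 (SD, n = 4 each). This scale understates the change of genes dimmer when untreated, such as IDO1 and IFNB1. The largest fall was that of THBD, the anticoagulant receptor thrombomodulin, from 1003 ± 496 to 111.1 ± 67.6 (SD, n = 4 each), a log2 change of -3.14. Of 19775 genes, 778 were higher and 789 were lower after hY3 (limma, Benjamini-Hochberg adjusted p under 0.05), and 385 of the higher and 211 of the lower genes changed at least 2-fold. At least 4-fold changes were seen for 152 higher genes and 16 lower genes. The 4 hY3 arrays lay entirely above or below the 4 untreated arrays for 17.0% of all genes, against 2.86% from chance. With the array number as a block, 1451 genes were higher and 2390 lower. Without untreated array 2 there were 426 higher and 258 lower genes (279 and 88 at 2-fold), without hY3 array 2 there were 438 and 242 (284 and 87), and without untreated array 1 there were 455 and 274 (296 and 93). Without untreated array 3 or 4 or hY3 array 1 or 3 the lower genes numbered 520, 485, 458 and 512, and at 2-fold the lower genes numbered 132 without hY3 array 1 and 355 without hY3 array 4. Arrays numbered 1 and 2 alone gave 959 higher and 1326 lower genes, and arrays numbered 3 and 4 alone gave 137 and 16.

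**Figure D1:**
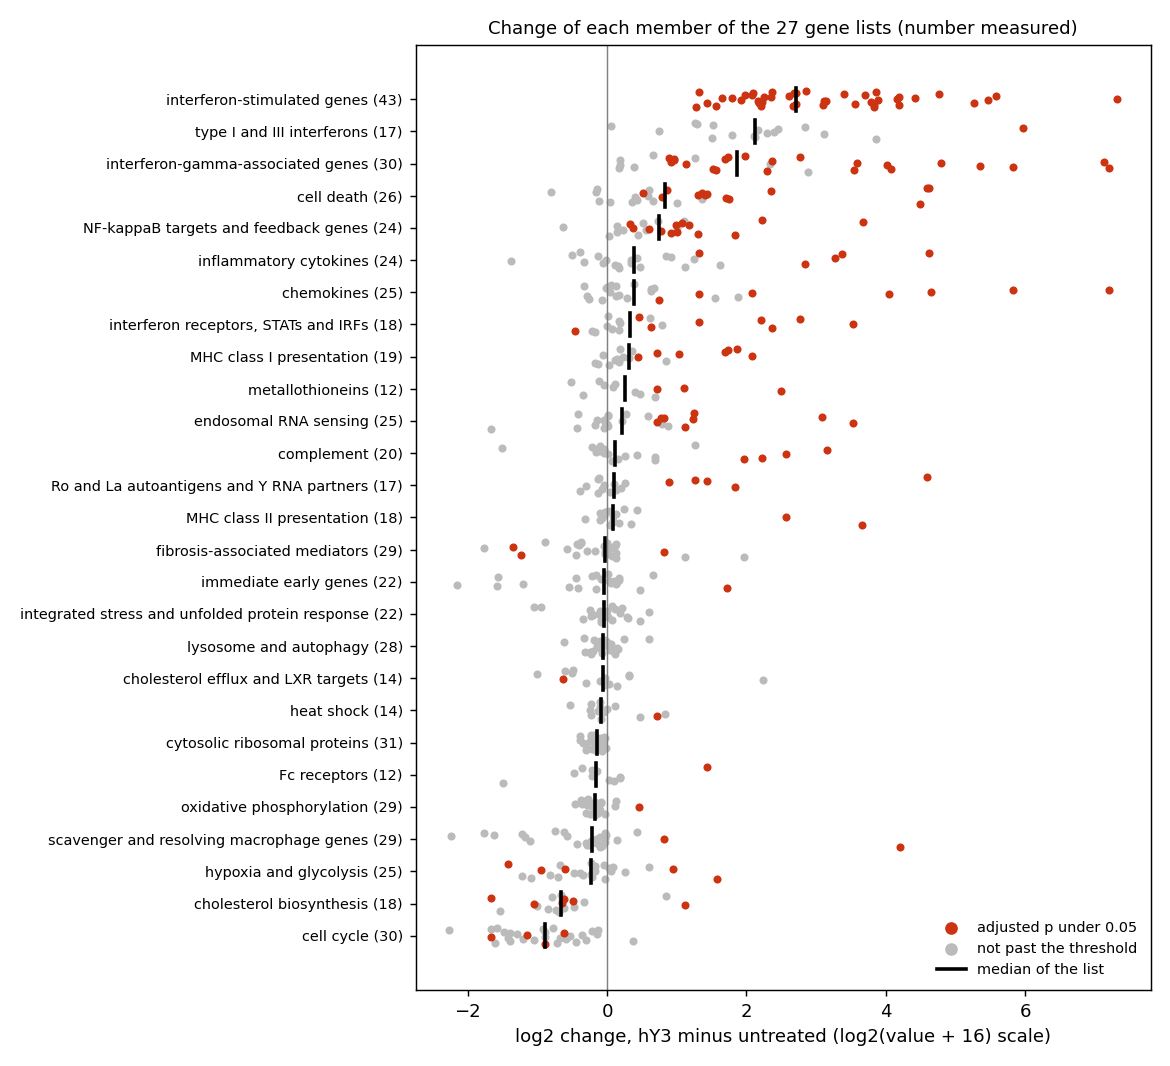
Log2 change (hY3 minus untreated, on the log2(value + 16) scale, x axis) of every measured member of the 27 gene lists (y axis, with the number measured), with members past an adjusted p of 0.05 in red, other members in grey and the median of each list as a black bar. All 43 interferon-stimulated genes lie to the right of 0 in red, and the medians of cholesterol biosynthesis (-0.66) and cell cycle (-0.89) lie furthest to the left.

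Interferon-stimulated genes are the antiviral genes that type I interferon switches on in most cells. MX1, a GTPase that blocks viral replication, rose from 699 ± 649 to 11808 ± 730 (SD, n = 4 each), a log2 change of 4.42 (adjusted p = 0.00332). IFIT1, which binds viral RNA, rose by 3.79 (adjusted p = 0.00365), the RNA helicase RIGI by 3.70 and OASL by 5.58. SIGLEC1, the sialic acid receptor CD169 of macrophages, rose from 1938 ± 1108 to 7577 ± 1261 (SD, n = 4 each), a log2 change of 2.09 (adjusted p = 0.0123). The list shifted upward against other genes (camera adjusted p = 1.79e-50, but adjusted p = 0.123 with an estimated correlation). Its median log2 change was 2.92 in arrays numbered 1 and 2 and 2.71 in those numbered 3 and 4. Untreated array 1 stood apart, with a mean log2 level of the list of 10.00 against 8.92 to 9.14 on the other untreated arrays and an MX1 intensity of 1662 against 241 to 458, and the median difference was 2.48 for number 1 and 3.28 for number 2.

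Of the 17 type I and III interferon genes measured, IFNB1, which encodes interferon-β, rose, from 8.45 ± 2.41 to 3283 ± 3579 (SD, n = 4 each; log2 change 5.98, adjusted p = 0.0156). The 4 hY3 arrays read 7721, 4652, 442 and 319 for IFNB1 in order of their number, against at most 11.8 on any untreated array. Without untreated array 2 the adjusted p of IFNB1 was 0.0511. The other 16 members did not pass the test. Among them the interferon-α gene IFNA1 differed by 3.86 (adjusted p = 0.129, or 0.0445 without hY3 array 4), IFNA17 by 1.79 (adjusted p = 0.187) and the type III gene IFNL1 by 1.52 (adjusted p = 0.167). The median change of the list was 2.13 (camera adjusted p = 1.53e-05, and adjusted p = 0.443 with an estimated correlation). It was 3.88 in arrays numbered 1 and 2, where 13 members passed the test, and 0.32 in arrays numbered 3 and 4, where 1 passed. Interferon-α genes are close copies of each other, so their probe sets may not be told apart in full.

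Genes associated with interferon-γ rose for 22 of 30 measured members, and for 27 with p-values adjusted over the list alone. The chemokine CXCL10, which attracts T cells, rose by 7.20 (adjusted p = 7.52e-04), IDO1, which breaks down tryptophan, by 7.13 (adjusted p = 8.69e-04) and CXCL11 by 5.83. The guanylate-binding proteins GBP1 and GBP4, which act against intracellular pathogens, rose by 4.02 and 4.80, and the transcription factor BATF2 by 4.08. CXCL9, another interferon-γ-induced chemokine, did not pass the test, at 3104 ± 996 untreated and 4604 ± 2701 after hY3 (SD, n = 4 each). CXCL9 was chosen after its values were seen. The list's median was 1.86 (camera adjusted p = 3.36e-28, and adjusted p = 0.123 with an estimated correlation), with 2.34 in arrays numbered 1 and 2 and 1.53 in those numbered 3 and 4. Among interferon receptors, STATs and IRFs, 7 of 18 measured members rose and 1 fell (9 and 2 adjusted over the list alone), with a median of 0.40 in arrays numbered 1 and 2 and 0.25 in 3 and 4. IRF7, the transcription factor that amplifies type I interferon, rose by 3.54, IRF1 by 2.37, the kinase JAK2 by 2.21 and IRF9 by 1.32. The member that fell was IFNGR1, a chain of the interferon-γ receptor, with a log2 change of -0.46 (adjusted p = 0.0368), named after its values were seen. This list passed camera (adjusted p = 4.01e-05, and adjusted p = 0.156 with an estimated correlation).

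**Figure D2:**
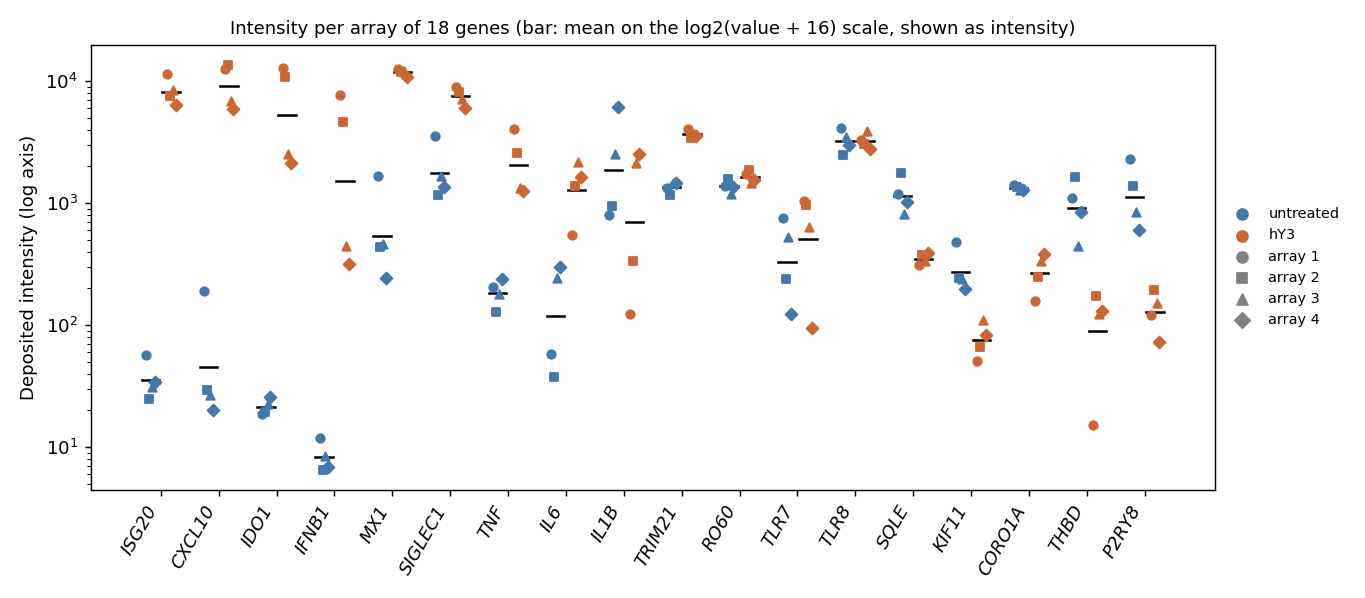
Deposited intensity (y axis, log scale) of 18 named genes (x axis) on each array, in blue for untreated and orange for hY3, with a marker shape for each array number and a bar at the mean taken on the log2(value + 16) scale. IFNB1 and IDO1 are brighter on hY3 arrays 1 and 2 than on hY3 arrays 3 and 4, and MX1 lies between 10788 and 12464 on all 4 hY3 arrays.

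Of 24 inflammatory cytokines measured, 5 rose (6 adjusted over the list alone) and none fell, while with the array number as a block 8 rose and 2 fell. TNFSF10, the death ligand TRAIL, rose by 4.62 (adjusted p = 1.92e-04). TNF rose from 188 ± 47.0 to 2297 ± 1291 (SD, n = 4 each), a log2 change of 3.37 (adjusted p = 0.00322). IL15, a growth factor of NK and T cells, rose by 2.84 and TNFSF13B, the B cell survival factor BAFF, by 1.31. IL6 rose by 3.27 (adjusted p = 0.0296), but did not pass without untreated array 1 or 2 or without hY3 array 2, 3 or 4, with adjusted p up to 0.0834. IL1B did not pass, at 2591 ± 2470 untreated and 1273 ± 1218 after hY3 (SD, n = 4 each; log2 change -1.38, adjusted p = 0.503, or 0.0571 with the array number as a block), with the hY3 array the lower in each of the 4 pairs of the same number. The list passed camera (adjusted p = 8.97e-05, and adjusted p = 0.156 with an estimated correlation), with a median of 0.68 in arrays numbered 1 and 2 and 0.17 in those numbered 3 and 4. Of 25 chemokines, 7 rose with either adjustment, among them CCL8, from 1114 ± 1050 to 19219 ± 3604 (SD, n = 4 each), and CCL5, which rose by 4.04. The chemokine list passed camera (adjusted p = 9.37e-05, and adjusted p = 0.123 with an estimated correlation), with a median of 0.54 in arrays numbered 1 and 2 and 0.09 in those numbered 3 and 4. Of 24 NF-κB targets and feedback genes, 13 rose (17 adjusted over the list alone), with TRAF1 at 2.22, the costimulatory receptor CD40 at 1.84 and the inhibitor NFKBIE at 0.61 (camera adjusted p = 7.71e-12, and adjusted p = 0.156 with an estimated correlation). The median of the NF-κB list was 1.15 in arrays numbered 1 and 2 and 0.36 in those numbered 3 and 4. With the array number as a block 15 of its members rose and 1 fell.

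Endosomal RNA sensing genes rose for 8 of 25 members with either adjustment (camera adjusted p = 6.13e-04, and adjusted p = 0.225 with an estimated correlation), with a median of 0.32 in arrays numbered 1 and 2 and 0.01 in 3 and 4. TLR3, a receptor for double-stranded RNA, rose by 3.09 (adjusted p = 0.00134), the chaperone UNC93B1 by 1.25 and the adaptor MYD88 by 0.72. With the array number as a block 10 members of this list rose and 1 fell. The single-stranded RNA receptors did not pass the test. TLR7 read 409 ± 284 untreated and 687 ± 432 after hY3 (SD, n = 4 each; adjusted p = 0.737), and TLR8 read 3255 ± 705 and 3244 ± 474 (SD, n = 4 each; adjusted p = 0.984). Of 17 Ro and La autoantigens and Y RNA partners, 5 rose, or 5 higher and 1 lower adjusted over the list alone, with a median of 0.10, or 0.25 in arrays numbered 1 and 2 and -0.002 in 3 and 4 (camera adjusted p = 0.0303, and adjusted p = 0.156 with an estimated correlation). The camera adjusted p of this list was 0.0738 without hY3 array 2 and 0.355 without probe sets of the _x_at and _s_at kind, and with the array number as a block 6 members rose and 2 fell. The members that rose are also known as interferon-induced or RNA-handling genes: ZBP1, a sensor of Z-form nucleic acid, rose by 4.59, the helicase MOV10 by 1.83, the exonuclease XRN1 by 1.26 (2.51 with its most variable probe set), SSB, the La protein, by 0.89, and TRIM21, the Ro52 autoantigen, by 1.44 (adjusted p = 2.26e-04). SSB was named after its values were seen. RO60 itself read 1380 ± 158 untreated and 1654 ± 189 after hY3 (SD, n = 4 each; log2 change 0.26, adjusted p = 0.204, or 0.0302 with the array number as a block). The probe sets of RO60 disagreed: without those whose identifiers end in _x_at or _s_at the log2 change was -0.16.

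Antigen presentation by MHC class I rose for 7 of 19 members (9 adjusted over the list alone; camera adjusted p = 5.55e-06, and adjusted p = 0.156 with an estimated correlation), with a median of 0.41 in arrays numbered 1 and 2 and 0.21 in 3 and 4. The transactivator NLRC5 rose by 2.09, the peptide transporter genes TAP1 and TAP2 by 1.74 and 1.86, and the proteasome subunit PSMB9 by 1.69. Of 18 MHC class II presentation genes, 2 rose with either adjustment, the costimulatory molecule CD80 by 3.67 and HLA-DOB by 2.57, and the list did not pass camera (adjusted p = 0.0697), but did without untreated array 1 (0.0150) or 2 (0.0479) or hY3 array 4 (0.0112), and with a filter on dim probe sets (0.0361). HLA-DOB did not pass without untreated array 1, 2 or 4 or without hY3 array 2, with adjusted p up to 0.0732, and its log2 change was 0.31 (adjusted p = 0.0745) without probe sets of the _x_at and _s_at kind. Of 20 complement genes, 4 rose (5 adjusted over the list alone): the alternative pathway factor CFB by 3.16, C5 by 2.57, and the C1 proteases C1S and C1R by 2.23 and 1.96 (camera adjusted p = 0.0316, and adjusted p = 0.156 with an estimated correlation). The median of the complement list was 0.17 in arrays numbered 1 and 2 and 0.08 in 3 and 4. The complement list did not pass without probe sets of the _x_at and _s_at kind (adjusted p = 0.0806). CFB did not pass without untreated array 2 or hY3 array 2, with adjusted p up to 0.0555. Without the _x_at and _s_at probe sets the log2 change was 0.64 for CFB (adjusted p = 0.0217) and 1.23 for C1S (adjusted p = 0.0388). Of 12 Fc receptor genes, TRIM21, an intracellular antibody receptor, alone rose (1 higher and 1 lower adjusted over the list alone, 1 and 2 with the array number as a block). The list did not pass camera (adjusted p = 0.905), and its median was -0.16 although the test pointed up. FCAR, the IgA receptor, read 113 ± 62.1 and 28.6 ± 17.2 (SD, n = 4 each; log2 change -1.49, adjusted p = 0.0753, or 0.0398 with the array number as a block), and the log2 change was -0.47 over the mean of its probe sets.

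Cell death genes rose for 13 of 26 members, or 16 higher and 1 lower adjusted over the list alone, with a median of 0.83 (camera adjusted p = 1.62e-11, and adjusted p = 0.123 with an estimated correlation). Its median was 1.08 in arrays numbered 1 and 2 and 0.59 in those numbered 3 and 4. AIM2, a cytosolic DNA sensor that forms an inflammasome, rose by 4.50 (adjusted p = 9.40e-05), and ZBP1 and TNFSF10 belong to this list too. CFLAR, an inhibitor of caspase-8, rose by 1.30 with the probe set used, while the log2 change was -0.03 without probe sets of the _x_at and _s_at kind and the adjusted p was 0.107 with the most variable probe set. The metallothionein list had 12 measured members, among them MTF1, SLC30A1, SLC39A8 and SLC39A14, which are not metallothioneins. Of the 12 members, 3 rose with either adjustment, MT1M by 2.49, MT2A by 1.11 and MT1X by 0.72. This list passed camera (adjusted p = 0.0303, and adjusted p = 0.501 with an estimated correlation), but not without untreated array 4 (adjusted p = 0.101) or hY3 array 2 (adjusted p = 0.0701) or without probe sets of the _x_at and _s_at kind (adjusted p = 0.871). In arrays numbered 1 and 2 alone its camera adjusted p was 0.266, with a median of 0.12 against 0.52 in 3 and 4. MT1X did not pass over the mean of its probe sets (adjusted p = 0.180) or with the most variable (0.0518), and passed in 1 of the 8 fits that each left out an array. Neither the heat shock list (camera adjusted p = 0.670, with a median of -0.09, a mean of 0.03 and a test that pointed down) nor the integrated stress and unfolded protein response list (0.905) nor the immediate early genes (0.905) passed. DNAJA1, a cochaperone in the heat shock list, rose by 0.72, or by 1.11 with its most variable probe set (1 higher and 1 lower adjusted over the list alone), and DUSP5, a phosphatase of ERK among the immediate early genes, by 1.72, the member that rose with either adjustment. No integrated stress gene passed with either adjustment, and with the array number as a block 3 rose and 1 fell. Other choices of probe set gave calls. ATF3 passed over the mean of its probe sets (log2 change 0.60, limma adjusted p = 0.0164) and with the most variable (0.84, adjusted p = 0.0299). Over the mean of their probe sets PPP1R15A (0.61, adjusted p = 0.0436) and TRIB3 (-0.60, adjusted p = 0.0342) passed too. Of the immediate early genes 2 rose and 1 fell with the block. FOS read 3836 ± 410 and 1205 ± 1015 (SD, n = 4 each; adjusted p = 0.105).

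Cell cycle genes fell for 4 of 30 members over all genes, and for 18 adjusted over the list alone, with a median of -0.89. The mitotic kinesin KIF11 fell from 290 ± 129 to 77.4 ± 25.6 (SD, n = 4 each; log2 change -1.67, adjusted p = 0.0177), the replicative helicase subunits MCM2 and MCM7 had changes of -1.15 and -0.61 and the mitotic kinase AURKA of -0.90. With the array number as a block 11 members fell and 1 rose. The list passed camera (adjusted p = 1.29e-08, and adjusted p = 0.317 with an estimated correlation), with a median of -1.21 in arrays numbered 1 and 2 and -0.53 in those numbered 3 and 4. KIF11 did not pass without untreated array 2 or hY3 array 2 (adjusted p up to 0.0588), MCM2 without untreated array 1 or hY3 array 2 (up to 0.0565), and MCM7 passed in 2 of the 8 fits that each left out an array. The change of MCM7 was -0.93 with its most variable probe set. Of 18 cholesterol biosynthesis genes, 5 fell and 1 rose, or 13 and 2 adjusted over the list alone and also with the array number as a block. SQLE, which makes squalene epoxide, fell from 1196 ± 415 to 352 ± 37.7 (SD, n = 4 each; log2 change -1.67, adjusted p = 0.00590), and MVD and SC5D had changes of -0.65 and -0.62. LSS, which closes the sterol ring, rose by 1.12 (adjusted p = 0.0341), against the direction of the list. The list's median was -0.66 (camera adjusted p = 2.12e-05, and adjusted p = 0.198 with an estimated correlation), with -0.90 in arrays numbered 1 and 2 and -0.45 in those numbered 3 and 4. SC5D did not pass without untreated array 1 or hY3 array 2 (adjusted p up to 0.0618), MVD without untreated array 3 or hY3 array 2 (up to 0.0633), and LSS passed in 2 of the 8 fits that each left out an array. With the mean of a gene's probe sets or the most variable probe set neither LSS (adjusted p = 0.233 and 0.464) nor SC5D (0.188 and 0.474) passed. Cholesterol efflux and LXR target genes did not pass camera (adjusted p = 0.502), with 1 of 14 lower over all genes, 1 higher and 2 lower adjusted over the list alone, and 2 higher and 3 lower with the array number as a block. Of these, FASN, fatty acid synthase, fell by 0.63, though not without untreated array 1 or 2 or hY3 array 2 or 3 (adjusted p up to 0.0638) nor over the mean of its probe sets (0.123), and the gene CH25H, whose enzyme makes 25-hydroxycholesterol, read 194 ± 99.3 and 1082 ± 800 (SD, n = 4 each; adjusted p = 0.0513, or 0.0153 with the array number as a block and 0.0222 without hY3 array 4).

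Macrophage and monocyte markers had a median of -0.48 (camera adjusted p = 0.0305, and adjusted p = 0.317 with an estimated correlation), with a camera adjusted p of 0.0527 without untreated array 2 and of 0.153 with a filter on dim probe sets. The median was -0.79 in arrays numbered 1 and 2 and -0.18 in those numbered 3 and 4 (camera adjusted p = 0.0941). Of 14 markers, CSF1R, the receptor for the growth factor M-CSF, fell (log2 change -0.92, adjusted p = 0.0204) and the rest did not pass, with the same count adjusted over the list alone. No marker passed without untreated array 2. With the array number as a block 3 markers fell. CSF1R was named after its values were seen. Scavenger and resolving macrophage genes as a list did not pass camera (adjusted p = 0.179, or 0.0435 without hY3 array 3). Of 29 members 2 rose, or 2 higher and 1 lower adjusted over the list alone and 2 and 2 with the array number as a block. AXL, a receptor for dying cells, rose from 25.9 ± 3.14 to 981 ± 706 (SD, n = 4 each; log2 change 4.20, or 2.50 over the mean of its probe sets), and the IL-10 receptor chain IL10RA rose by 0.82. IL10RA did not pass without untreated array 1 or 2 or hY3 array 2 (adjusted p up to 0.0613). The gene MERTK, for a receptor of the same family as AXL, read 1551 ± 313 untreated and 414 ± 293 after hY3 (SD, n = 4 each; log2 change -2.23, adjusted p = 0.0720, or 0.0260 with the array number as a block, 0.0497 without hY3 array 1, 0.0489 without hY3 array 4 and 0.0491 over the mean of its probe sets). Without probe sets of the _x_at and _s_at kind the log2 change of MERTK was -0.05 (adjusted p = 0.698). The lipid-sensing factor gene PPARG read 1911 ± 336 and 684 ± 354 (SD, n = 4 each; adjusted p = 0.0571, or 0.0443 with the block, 0.0394 without hY3 array 1 and 0.0476 without hY3 array 4). Of 29 fibrosis-associated mediators, 1 rose, the matrix protease MMP14 (log2 change 0.81), and 2 fell, the growth factor HBEGF (-1.24) and the protease urokinase, PLAU (-1.35), and the list did not pass camera (adjusted p = 0.470). These counts were the same adjusted over the list alone, and with the array number as a block 4 fell. HBEGF and PLAU passed in 2 of the 8 fits that each left out an array, and HBEGF did not pass over the mean of its probe sets (log2 change -0.60, adjusted p = 0.0698). EDN1, endothelin-1, did not pass, at 89.9 ± 31.4 and 265 ± 203 (SD, n = 4 each; adjusted p = 0.279, or 0.0575 with the array number as a block). Its hY3 array was the higher in each pair of the same number, with a log2 change of 1.77 in numbers 1 and 2 and 0.48 in 3 and 4. TGFB1 read 531 ± 164 and 587 ± 215 (SD, n = 4 each; adjusted p = 0.871).

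The lists of ribosomal proteins and oxidative phosphorylation changed little in size. The median was -0.14 for cytosolic ribosomal proteins, where no member passed the test (camera adjusted p = 8.16e-05, and adjusted p = 0.317 with an estimated correlation), and -0.17 for oxidative phosphorylation (camera adjusted p = 0.00457, and adjusted p = 0.633 with an estimated correlation). NDUFA9, a complex I subunit, rose by 0.46, against the direction of the list, and passed in 1 of the 8 fits that each left out an array. Adjusted over the list alone, no oxidative phosphorylation gene passed, and with the array number as a block 5 fell, beside 1 ribosomal protein gene. With a filter on dim probe sets the camera adjusted p of the oxidative phosphorylation list was 0.153. In arrays numbered 3 and 4 alone, neither list passed camera (adjusted p = 0.128 and 0.0569). Of 25 hypoxia and glycolysis genes, 2 rose and 3 fell, or 2 and 4 adjusted over the list alone and 2 and 6 with the array number as a block (camera adjusted p = 0.0687, or 0.0483 with the block). Its camera adjusted p was 0.0331 without untreated array 1, 0.0268 without untreated array 3 and 0.0282 without hY3 array 4. ADM, the peptide adrenomedullin, rose by 1.57 and PFKFB3, an activator of glycolysis, by 0.95. The glucose transporter SLC2A3, named after its values were seen, had a change of -1.43, PDK1, which inhibits pyruvate dehydrogenase, of -0.95 and PFKFB4 of -0.61. PFKFB4 passed in 1 of the 8 fits that each left out an array. Over the mean of their probe sets the change of PDK1 was -0.59 (adjusted p = 0.0171) and that of PFKFB4 was -0.35 (adjusted p = 0.0555). No lysosome and autophagy gene passed with either adjustment, while 2 rose and 3 fell with the array number as a block, and the list did not pass camera (adjusted p = 0.591).

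The genes of largest fall besides THBD were P2RY8, a G protein-coupled receptor, at -2.99, the G protein signalling regulator RGS18 at -2.85, ENC1 at -2.60, the calcium channel subunit CACNA2D3 at -2.44, the cell cycle transcription factor E2F2 at -2.38, GPR82 at -2.36 and CD93 at -2.35. They were followed by the folate transporter SLC46A1 at -2.26, the actin-binding protein CORO1A at -2.25, LRRC25 at -2.24 and TMC8 at -2.14. CORO1A went from 1332 ± 63.3 to 280.4 ± 98.9 (SD, n = 4 each; adjusted p = 0.00244). Over the mean of their probe sets the changes were smaller for E2F2 (-0.76), SLC46A1 (-1.05), TMC8 (-0.92) and CD93 (-1.55), and still passed. P2RY8, ENC1, E2F2, SLC46A1, CORO1A and TMC8 passed whichever array was left out. THBD (without untreated array 1, 2 or 4 or hY3 array 3), RGS18 (untreated 1, 2 or 3 or hY3 2), CACNA2D3 (untreated 2 or any hY3 array), GPR82 (any untreated array or hY3 2), CD93 (untreated 1 or any hY3 array) and LRRC25 (untreated 2 or hY3 2) did not, with adjusted p up to 0.0755, 0.0634, 0.0860, 0.0771, 0.0970 and 0.0553. The 12 largest rises included the interferon-stimulated genes IFITM1 (5.47) and IFI44L (5.27), ETV7 (5.35) of the interferon-γ list, and PDGFRL (6.23), NEXN (5.18) and STAP1 (5.18), which were in none of the lists.

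Markers of other cell types stayed dim or did not move as lists. The lists of T cells (camera adjusted p = 0.905), B and plasma cells (0.470), neutrophils (0.905), dendritic cells (0.670), platelets and megakaryocytes (0.235), erythroid cells (0.387) and fibroblasts and endothelium (0.591) did not pass camera. The test pointed up for neutrophils although median and mean lay below 0, and for fibroblasts and endothelium although the mean did. The NK cell list did (adjusted p = 0.0320, but 0.225 with an estimated correlation and 0.0648 with the array number as a block), with a median of 0.11, or 0.25 in arrays numbered 1 and 2 and 0.10 in 3 and 4, where it did not pass (adjusted p = 0.128). Without untreated array 2 its adjusted p was 0.0923, without hY3 array 1 it was 0.0666, with quantile normalisation 0.0553, with a filter on dim probe sets 0.383, and without probe sets of the _x_at and _s_at kind 0.115. Single markers that passed were named after their values were seen. They were SH2D1B (NK; 6.60 ± 0.70 to 16.9 ± 4.52), PAX5 (B cell; 16.1 ± 1.92 to 356 ± 297), CCR7 (dendritic cell; 23.1 ± 4.62 to 1443 ± 1609) and GP1BA (platelet; 203 ± 90.7 to 1147 ± 511), which rose, and TREML1 (platelet; 260 ± 18.2 to 129 ± 52.5), which fell (SD, n = 4 each). The SH2D1B values lie near or under the lower quartile of 12.1 to 12.8, and cannot be told from background. With the array number as a block 1 fibroblast and endothelial marker fell.

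**Figure D3:**
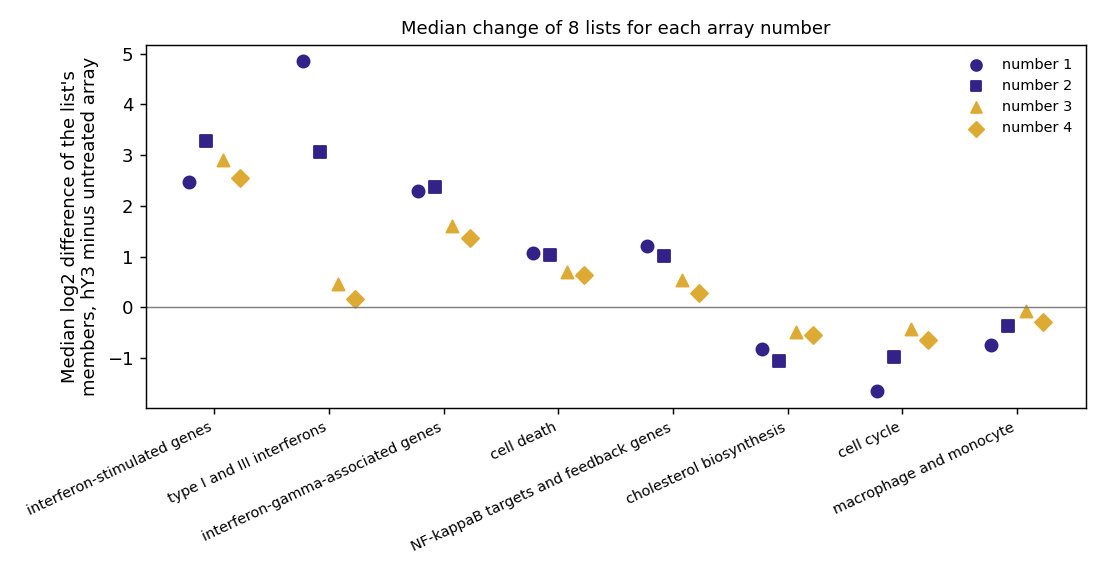
Median log2 difference between the hY3 and the untreated array of the same number (y axis), over the measured members of 8 lists (x axis), with numbers 1 and 2 in purple and 3 and 4 in yellow. The type I and III interferons stand at 4.85 and 3.06 for numbers 1 and 2 and at 0.47 and 0.16 for numbers 3 and 4, while the interferon-stimulated genes lie between 2.48 and 3.28 for all 4 numbers.

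The comparison of arrays asked whether they split by group or by number. The first principal component held 55.4% of the variance and separated hY3 from untreated arrays, and the next held 21.7% and separated numbers 1 and 2 from 3 and 4 in both groups. On the first component hY3 arrays 1 and 2 (scores 69.9 and 51.7) also stood apart from hY3 arrays 3 and 4 (14.5 and 4.5). The untreated arrays lay between -41.8 and -26.6 there, so the first component does not hold the treatment alone. ISG20, CXCL10, IDO1 and IFNB1 were higher on every hY3 array than on any untreated array. The rule for the largest rises took only such genes, so this says nothing on how the arrays split. IDO1 and IFNB1 were also higher on hY3 arrays 1 and 2 than on 3 and 4, with log2 changes of 8.39 and 5.87 for IDO1, a difference that did not pass the interaction test (adjusted p = 0.110). Pearson correlations across genes, which are not independent replicates, were 0.984 to 0.993 between untreated arrays, 0.971 to 0.991 between hY3 arrays and 0.949 to 0.987 across groups. The log2 ratio of the 3' to the 5' GAPDH control probe sets, a measure of RNA integrity that is higher in more degraded RNA, was 0.272 ± 0.045 in untreated and 0.418 ± 0.081 in hY3 arrays (SD, n = 4 each; two-sided exact permutation p = 0.0286, the smallest these arrays allow), and higher in 4 of 4 pairs of the same number. The same ratio of ACTB was 1.28 ± 0.29 and 1.66 ± 0.23 (SD, n = 4 each; two-sided exact permutation p = 0.114; 2 ratios were compared and the p-values are unadjusted), and it too was higher in 4 of 4 pairs, by 0.241 to 0.593. The p-values above ignore the pairing; by swaps within the 4 pairs, a test added after the data were seen, the two-sided exact permutation p was 0.125 for either ratio, the smallest that such swaps allow. Both ratios were higher with hY3 in the same arrays in which the cell cycle, cholesterol biosynthesis and macrophage marker lists were lower. The ribosomal protein and oxidative phosphorylation lists were lower there too, by less.

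**Figure D4:**
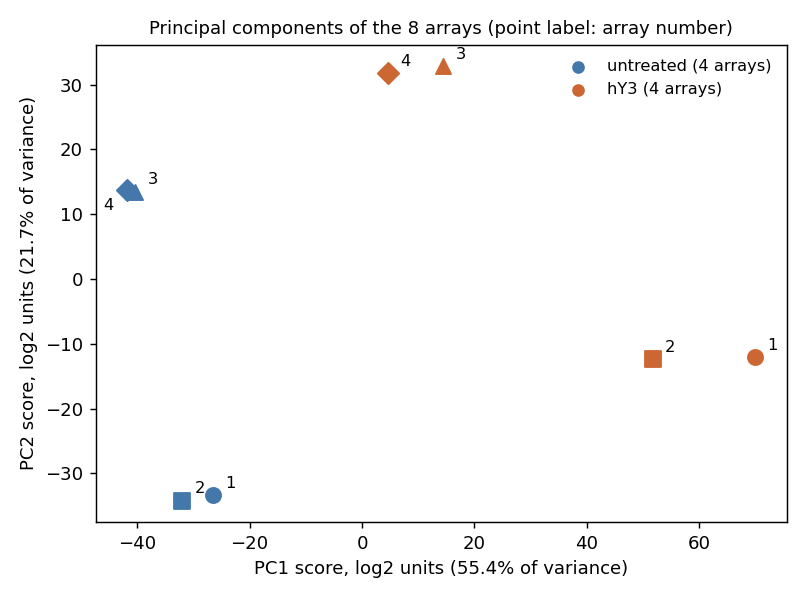
Scores of the 8 arrays on the first principal component (x axis, 55.4% of variance) and the next (y axis, 21.7% of variance), in log2 units, with untreated arrays in blue, hY3 arrays in orange and the array number beside each point. hY3 arrays lie to the right of the untreated arrays, and arrays numbered 3 and 4 lie above those numbered 1 and 2.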

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

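The tests of the patterns weighed here were chosen after the results were seen, except the counts over other splits of the arrays. An array was marked where its gap to the nearest array of its group exceeded the 95% critical value of Dixon's test as a share of the group's range on the log2 scale. Of 334 group tests 10 were marked, against 16.7 from chance at 1 in 20, so the marks as a set are no more than chance gives.

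CXCL10 was highest on untreated array 1 (ratio 0.868), which read 190.2 against 20.2 to 29.6 on the other untreated arrays, and IFIT1 read 1399 there against 292 to 557. RNA of hY3-treated cells in that sample was tested on 24 genes outside the interferon-stimulated list that read under 50 on average over untreated arrays 2 to 4 and over 1000 on hY3 array 1. Their median excess on untreated array 1 was 0.122% of the signal of hY3 array 1 (quartiles -0.013% and 1.10%), while the 43 interferon-stimulated genes showed 8.94%, which argues against carried-over RNA as the whole source. What raised these genes on that array stays open, since no label sets it apart, and no biological explanation was tested.

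C1S was lowest on hY3 array 4 (ratio 0.889), PPP1R15A was highest on hY3 array 1 (0.848), and MCM7 (0.866) and SC5D (0.923) were lowest on hY3 array 2. XRN1 was lowest on untreated array 3 (0.878), PFKFB4 on untreated array 1 (0.925) and TMC8 on untreated array 4 (0.842). THBD was lowest on hY3 array 1 (0.833), and the mean of the NF-κB targets and feedback genes was highest on untreated array 4 (0.938).

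The count of genes between hY3 and untreated arrays was compared with the other splits of the 8 arrays into 4 and 4. The real split gave 1567 genes and 1 of 35 splits, the real one, reached that, but these splits do not keep the pairing of the numbers. The highest other split, 1259 genes, set numbers 1 and 2 of both groups against 3 and 4, which points to a structure of the arrays besides the treatment. Of the 8 splits that part all 4 pairs, as the real one does, the other 7 called 0 genes by limma, and 8 are too few for a share under 0.05. With the array number as a block, the real assignment called 3841 genes and the highest of the 7 other swaps within pairs 0, and 1 of 8 assignments is too few for a share under 0.05.

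The smaller change of type I and III interferon genes in arrays numbered 3 and 4 was weighed against array scaling or a general loss of contrast. The interferon-stimulated genes kept 92.9% of their median change there, and the 11 of them under 5000 on every hY3 array kept 91.1%, while the interferon genes kept 8.35%. Against number 2 alone, which leaves out the raised untreated array 1, the shares were lower for the former (82.6% and 89.9%) and 10.6% for the latter. This argues against a scaling that acts on all genes alike. The interferon genes had a median untreated intensity of 8.16, under the lower quartile, so their share is imprecise. The interferon-γ-associated genes kept 65.6%, cell death genes 54.9%, NF-κB targets 31.0%, inflammatory cytokines 25.6% and chemokines 17.0%. A loss of contrast that reached most rising lists but spared the interferon-stimulated genes is therefore not excluded. A different donor, day or batch stays open: untreated arrays also differed between these numbers, with a lowest correlation within 1 and 2 or 3 and 4 that was 0.0048 above the highest across them, a value consistent with such a difference before treatment. No gene passed limma's interaction test of a different change between these numbers (0 at adjusted p under 0.05). All 3 of 3 divisions of the numbers gave 0, and 3 are too few for a share under 0.05. Of 19775 genes, 3011 had an unadjusted p under 0.05, more than the share of 0.05 that chance gives on average. With 8 arrays this fit has few residual degrees of freedom, so 0 calls do not show that the changes were alike. IFNB1 and CD93 shared the smallest adjusted p of the named genes, 0.0978, and IFNB1 had a change of 7.91 in numbers 1 and 2 and 4.05 in 3 and 4, while as a list the interferon genes differed by camera (adjusted p = 1.85e-16) but not by fry (adjusted p = 0.142). Other lists also differed by camera, among them interferon-γ-associated (adjusted p = 3.5e-13), NF-κB (1.95e-07) and cell cycle genes (3.0e-07). The interferon-stimulated genes did not (camera adjusted p = 0.336), and no list differed by fry.

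The lower cell cycle and macrophage marker genes were weighed against lower RNA integrity in the hY3 arrays. The GAPDH ratio rose by 0.229, 0.188, 0.086 and 0.079 in numbers 1 to 4 and the ACTB ratio by 0.593, 0.413, 0.241 and 0.290, beside cell cycle medians of -1.65, -0.98, -0.42 and -0.63 and macrophage marker medians of -0.73, -0.36, -0.07 and -0.28, so the falls were larger in numbers 1 and 2, the pairs with the larger rises, as lower integrity would give, and followed the order of the ACTB rises in all 4 pairs but not that of the GAPDH rises in 3 and 4. Cholesterol biosynthesis, at -0.81, -1.05, -0.47 and -0.55, also fell more in numbers 1 and 2, but more in 2 than in 1, against the order of both ratios. Ribosomal proteins (-0.23, -0.20, -0.06 and -0.06) and oxidative phosphorylation (-0.26, -0.23, -0.10 and -0.09) fell more in numbers 1 and 2 too. Numbers 1 and 2 also had the larger change of the interferon genes (4.85 and 3.06 against 0.47 and 0.16), and no pair without a rise exists, so the effect of RNA integrity and of hY3 on these lists cannot be told apart here. The response to hY3 itself stays open as the biological explanation, untested.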

How the results depend on the processing

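Fits on some of the numbers, with numbers 1 and 2 against 3 and 4 as a block, with a number left out and with block and estimated correlation or fry together were chosen after seeing the data. By construction, fits on fewer arrays and camera with an estimated correlation have fewer degrees of freedom, and stricter thresholds pass fewer genes. Other causes of the differences below were not tested. Against 778 higher and 789 lower genes (49.6% higher), the replicate block gave 1451 and 2390 (37.8% higher; 769 and 763 shared with the fit without it), as a random effect 1641 and 2369, and numbers 1 and 2 against 3 and 4 as a block 1329 and 2023. The replicate block with number 1, 2, 3 or 4 left out gave 907 and 1181, 324 and 152, 636 and 630, and 1201 and 1747. Only numbers 1 and 2 gave 1326 lower genes, and only numbers 3 and 4 gave 137 higher and 16 lower. Testing all probe sets gave 1642 and 1483, a 2-fold minimum 385 and 211, an adjusted p under 0.01 303 and 107, and treat against 1.2-fold 351 and 134. Leaving out 1 array gave 426 to 888 higher and 242 to 1029 lower genes: without untreated array 1 455 and 274, without untreated 2 426 and 258, without hY3 2 438 and 242, and lower genes numbered 520, 485, 458 and 512 without untreated 3, untreated 4, hY3 1 and hY3 3. Quantile normalisation, with 793 and 725, and median centring, with 764 and 828, moved neither count by 1.5 times.

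Of 36 lists, 19 passed camera; with an estimated correlation 0 did, with the replicate block 19 and with that block and an estimated correlation 0. With the block the NK cell list lost its call and hypoxia and glycolysis gained one, and no other list's call changed. Leaving out 1 array gave 17 to 21 lists. By fry the type I and III interferons (adjusted p = 0.115), oxidative phosphorylation (0.187) and metallothioneins (0.115) did not pass, and platelets and megakaryocytes did (0.0391). The ranges of adjusted p over all alternatives but the estimated correlation were up to 0.00848 for interferon-stimulated genes, 0.165 for type I and III interferons, 0.0275 for cholesterol biosynthesis, 0.0512 for cell cycle and 0.0415 for NF-κB targets. Lists were not run with the random block, which camera does not take.

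Of the 90 named genes past the threshold, 67 passed whichever array was left out. The replicate block ended no named gene's call and gave 12 new ones: CH25H, TFEB, ATF3, RO60, NDUFS3, FCGR2C, SMPDL3A, VEGFA, TRIB3, FCAR, PPARG and MERTK. Over all alternatives adjusted p ranged from 0.0302 to 0.923 for RO60, 0.0205 to 0.325 for FCAR, 0.00883 to 0.428 for CH25H, 0.0157 to 0.698 for MERTK and 0.0182 to 0.223 for PPARG. Without _x_at and _s_at probe sets the sign turned for CFLAR (-0.033), RO60 (-0.164), RPS6 (0.095) and FCGR2C (0.023), and with the most variable probe set for FCGR2A (0.082). TLR7 turned in numbers 3 and 4 (-0.025). TGFB1 ranged from -0.055 to 0.316 with 1 array left out. The gene TLR8, near 0 throughout, turned with quantile normalisation (-0.00994), the most variable probe set (-0.0025), numbers 1 and 2 (-0.0029), and the block without number 2 (-0.095) or 3 (-0.041), and ranged from -0.117 to 0.130 with 1 array left out. No detection calls were used, so signal over background limits what can be said of genes under about the median intensity.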

Other observations

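Genes outside the lists and the naming rule, chosen after their values were seen, filled in the picture of the treated macrophages. CD38, an enzyme that consumes NAD, rose from 45.3 ± 10.7 to 3545 ± 3321 (SD, n = 4 each; log2 change 5.12, limma adjusted p = 0.0142). IL15RA, the chain that presents IL-15 to other cells, rose by 4.15 (adjusted p = 1.91e-04) beside IL15 itself, and GCH1, which makes the cofactor tetrahydrobiopterin, by 3.91 (adjusted p = 1.33e-04). The lymphocyte activation markers CD69, LAG3 and SLAMF1 rose by 3.55, 3.63 and 3.46, the amino acid oxidase IL4I1 by 2.48 and CYP27B1, which activates vitamin D, by 2.61. Each of these was higher in 4 of 4 hY3 arrays than in every untreated array, as were 777 of the 778 genes called higher.

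Among falling genes chosen in the same way were receptors and transporters. The flagellin receptor TLR5 had a log2 change of -1.46 (adjusted p = 0.0351), the interleukin-1 receptor IL1R1 of -1.37 (adjusted p = 0.0167), the iron exporter SLC40A1 of -1.48 (adjusted p = 0.0410) and the membrane protein STEAP1 of -2.08 (adjusted p = 0.0367). PYGL, which breaks down glycogen, had a change of -1.32, and IGF1R and IRS1, of insulin-like growth factor signalling, of -1.25 and -1.46. Of the dendritic cell markers, and also picked after their values were seen, the lipid antigen presenters CD1A and CD1C did not pass the test, at -1.54 (adjusted p = 0.149) and -1.57 (adjusted p = 0.229).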
